A study of Homo sapiens with 8 samples.

How the data were processed

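Total RNA was purified with a column kit and treated with DNase I, and polyadenylated RNA was sequenced as paired ends by Novogene, per the labels. The authors' differential expression was computed by TAC genomics, per the labels. The genome build was hg19, per the submitters' processing notes; the aligner, the counting program and the software are not given in the sources used here. The authors deposited 1 table per lineage with a signal column per library, a signed fold column (resistant over sensitive, negative where lower) and columns holding a p-value and a false discovery rate. The deposited signal values are whole read counts divided by a scaled library size: within a tolerance of 0.02 reads, 100% of the values in each of the 8 libraries were whole multiples of the value of 1 read. The deposited false discovery rates were below 0.05 for 7773 genes of the C4-2B table (3817 higher, 3956 lower), 1464 of the CWR-R1 table (804 and 660) and 4594 of the VCaP table (2245 and 2349), by a test that the sources do not name. The deposited fold and p-value columns were not used further. Only genes that the authors called detectable are listed. The C4-2B table nevertheless lists 17 genes without a read in any of its libraries, against 0 in each other table. The rule behind its listing is therefore not known.

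Reads in the listed genes were recovered by dividing each signal value by the value of 1 read. They numbered 14503586 to 20248655 per library, and the 10 most abundant genes held 3.62% to 5.21% of them. A count of 3 reads, the floor used where a group had no read, corresponds to a level of 0.142 to 0.202. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Over genes with 50 or more reads the replicates differed more than counting error allows (chi-square per gene 3.99 in C4-2BENZR and 5.67 in C4-2B, against 1 for counting error alone).

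The groups, the tests, the named genes, the 38 gene lists and most alternatives were chosen before the data were examined. The unit differed from what the plan assumed. The plan named edgeR for counts and limma where the tables hold none, and a prior count of 2 for the single-library ratios. The tables hold scaled counts, so limma was used, with a pseudocount of 1 throughout. The prior count of 2 and edgeR on the recovered reads, with its own scaling (with and without a replicate block) or on reads summed per group, were run as alternatives chosen after seeing the data. edgeR with median-of-ratios size factors, with total counts only and on all 8 libraries with a lineage block had been chosen before. In C4-2B, log2(value + 1) of genes with a value of at least 1 in at least 2 libraries was fitted with limma (trend), 2 libraries against 2, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The replicate numbers of the labels do not say what replicates share, so the main model had no block; a replicate block was an alternative. For CWR-R1 and VCaP, with 1 library per group, log2 ratios of value + 1 were compared among genes with a value of at least 5 in one of both libraries, and differences of at least 2-fold were counted without a test; 95% intervals of single ratios are exact binomial (Clopper-Pearson). Across the lineages, limma was fitted to the 3 within-table log2 ratios of the 12868 shared genes, with the C4-2B replicates averaged.

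The lists held 903 genes, of which 792 were listed in a table, 2 of them under another symbol; 37 lists had a listed gene, and that of transcripts encoded by the mitochondrial genome had none. Lists of at least 5 measured members were tested with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg adjustment over the lists), and again with an estimated correlation and with fry, which passed 23 lists on balance in 1 direction and 34 for change in either direction. In the single-library lineages the median of a list was placed among 10000 random lists of the same size matched on mean expression. Named genes were the 8 highest and 8 lowest by log2 ratio in each lineage (adjusted p below 0.05, mean of at least 5 and groups that do not overlap in C4-2B; a sum of at least 10 in the other lineages), the 6 highest and 6 lowest by the smallest of the 3 absolute log2 ratios across lineages, 13 genes of androgen response and cell identity in every table (2 of them are not reported here), and for each list up to 4 members with the largest change and members that went the opposite way. Of the 8 lowest in C4-2B, 5 genes were left out and the next lowest took their place. Gene order was taken from the RefSeq annotation of GRCh38.p14, used for neighbours only.

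The alternatives were other scalings (median-of-ratios size factors, total counts only), other tests on recovered reads (edgeR, limma-voom, DESeq2), other filters, pseudocounts and thresholds, a replicate block, each library or lineage left out in turn and single C4-2B replicates. The VCaP lineage was left out of the overlap count as an alternative chosen after seeing the data. The procedures were tested on simulated data with 200 changed genes and a planted list. In the simulated C4-2B comparison (13156 genes), 65.7% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 95.2% of those changed 4-fold were called, and 7.39% of calls fell on unchanged genes. Across lineages (13092 genes), 6.59%, 55.2% and 100% were called, with 3 calls on unchanged genes. That simulation gave every gene the same spread between lineages. In the data BAMBI, with log2 ratios of 2.81, 3.70 and 3.05, had a limma adjusted p of 0.829. The simulated shares therefore overstate what the real comparison across lineages could find. For CWR-R1 only a list was planted (14809 genes). The planted lists were recovered in the simulated C4-2B, CWR-R1 and across-lineage comparisons, with 1, 1 and 0 unplanted lists beyond the threshold. The simulated genes varied independently of each other. These counts therefore do not show how often a list of correlated genes passes without a planted change. The tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.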

Results

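Polyadenylated RNA was sequenced in 8 libraries of prostate cancer cell lines, each line as an enzalutamide-sensitive and an enzalutamide-resistant (ENZR) form. Enzalutamide is an antiandrogen, a drug that blocks androgen signalling. C4-2B, a castration-resistant derivative of LNCaP, gave 2 sensitive and 2 resistant libraries of cells carrying luciferase and GFP transgenes. CWR-R1, derived from a relapsed prostate xenograft, and VCaP, derived from a vertebral metastasis and carrying a fusion of TMPRSS2 with ERG, gave 1 sensitive and 1 resistant library each. The reads in the listed genes numbered 20248655 and 16699735 in the C4-2BENZR replicates, 20008736 and 19956054 in the C4-2B replicates, 15249294 in CWR-R1, 14503586 in CWR-R1ENZR, 18171891 in VCaP and 16235796 in VCaPENZR. Levels below are reads scaled by library size as deposited, close to counts-per-million (CPM). The C4-2B, CWR-R1 and VCaP tables were normalized separately and listed 13969, 14809 and 14800 genes, of which 12868 stood in all 3.

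Across the 12868 shared genes, on log2 values and with the caution that genes are not independent replicates, the libraries of a C4-2B group correlated at 0.995 (C4-2BENZR) and 0.995 (C4-2B). C4-2B and C4-2BENZR libraries correlated at 0.948 to 0.949, and CWR-R1 and CWR-R1ENZR at 0.890. The library labelled VCaPENZR correlated at 0.940 with CWR-R1ENZR, at 0.890 with CWR-R1 and at 0.728 with VCaP, the sensitive line of its own table.

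**Figure D1:**
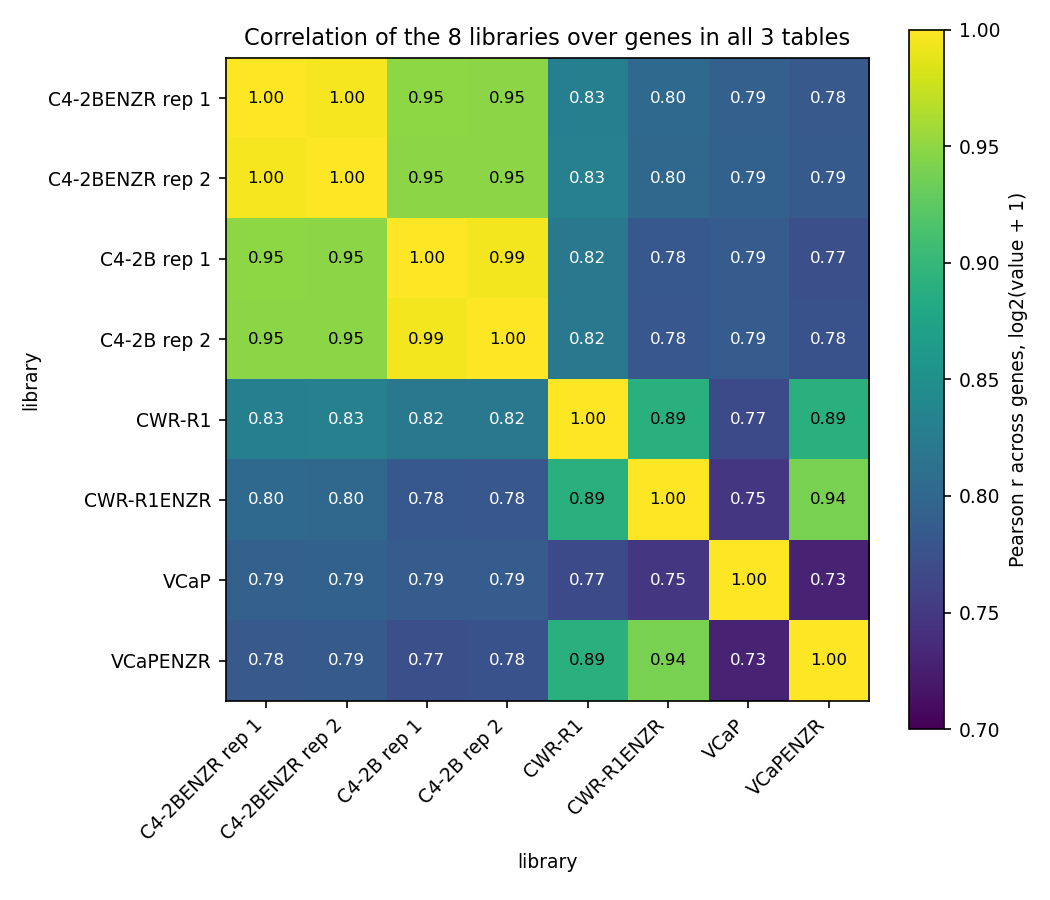
Pearson correlation of log2 values between the 8 libraries over the 12868 genes listed in all 3 tables, which were normalized separately. Each cell is 1 pair of libraries. The library labelled VCaPENZR is closest to CWR-R1ENZR (0.940) and farthest from VCaP (0.728).

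The first comparison asked which transcripts differed between C4-2BENZR and C4-2B. Genes activated by androgen moved in both directions. KLK3, which encodes prostate-specific antigen, fell 42.1-fold, from 2045 ± 30.3 in C4-2B to 48.6 ± 0.797 in C4-2BENZR (SD, n = 2 libraries per group; limma adjusted p = 1.47e-20). Among other such genes, FKBP5 rose 1.89-fold to 698 ± 8.32 and TMPRSS2 rose from 236 ± 2.31 to 294 ± 11.7. Of 28 measured androgen-activated genes, 16 rose and 9 fell, and as a list they did not pass the set test (median log2 change 0.22; camera adjusted p = 0.0588; without C4-2B replicate 2 it passed, with a median of 0.30 and an adjusted p of 0.0248, as it did with the replicate as a block, 0.0272, and with fry, 0.0495). NDRG1 rose from 68.8 ± 12.4 to 256 ± 15.5 and STEAP4, a metalloreductase, rose from 0.0517 (2 reads) to 8.66 ± 0.0468, while GNMT fell 3.76-fold. Genes that androgen withdrawal raises went the other way in 8 of 12 cases, among them DDC, which encodes aromatic L-amino acid decarboxylase and fell 6.98-fold, and CAMK2N1, which fell 5.30-fold. The other 4 rose, among them OPRK1, at least 12.4-fold, and ACKR3, 2.81-fold. That list had a median of −0.60 and a camera adjusted p of 0.119. It passed with total counts as the only scaling (0.0496) and with fry (0.00523). It also passed without either C4-2BENZR replicate, but on fewer members. OPRK1, at 0 in C4-2B, then missed the filter of a value of at least 1 in at least 2 libraries.

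Among the 8 highest genes, SSX2B, a cancer-testis gene whose reads may be shared with the near-identical SSX2, was at 97.2 ± 3.07 in C4-2BENZR against 3 reads in C4-2B, and VCX, another gene of the testis, was at 168 ± 1.74 against 1.55 ± 0.361. KCNJ3, an inwardly rectifying potassium channel, was at 74.8 ± 3.04 and had no read in C4-2B, so it was at least 431-fold higher against a floor of 3 reads per library. SYT4, a synaptotagmin of secretory vesicles, rose 71.6-fold from 5.32 ± 0.0597 to 381 ± 0.271, SEMA6A rose 90.5-fold, TENM2 rose from 5 reads to 41.6 ± 0.841, BEX1 from 1 read to 33.6 ± 4.23 and FSTL5 from 2 reads to 32.1. Among the lowest, the engulfment adaptor GULP1 fell from 98.5 ± 2.11 to 0.105 (4 reads), the protocadherin PCDH7 fell 75.5-fold from 225 ± 4.51, the coagulation inhibitor TFPI fell 73.8-fold, TM4SF1 fell 29.6-fold and CADPS2 fell 21.4-fold. The prostaglandin receptor PTGFR was at 26.5 ± 2.88 in C4-2B and had no read in C4-2BENZR, at least 153-fold lower, and PCDH20 went from 23.8 ± 0.0966 to 3 reads.

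Epithelial and mesenchymal markers also moved. VIM, which encodes the mesenchymal intermediate filament vimentin, rose 4.21-fold to 57.6 ± 2.15, CDH1, which encodes E-cadherin, fell 1.73-fold to 480 ± 12.3, and the luminal keratin KRT8 rose 1.54-fold to 499 ± 24.2. The proliferation marker MKI67 was at 250 ± 17.8 against 213 ± 38.7 (adjusted p = 0.0256), a call lost without C4-2BENZR replicate 1 (0.0573), without C4-2B replicate 2 (0.527) and with DESeq2 (0.340). SYP, which encodes synaptophysin, was at 0.984 against 1.29 and did not differ (adjusted p = 0.473). NR3C1, CHGA and ERG are not listed in this table.

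**Figure D2:**
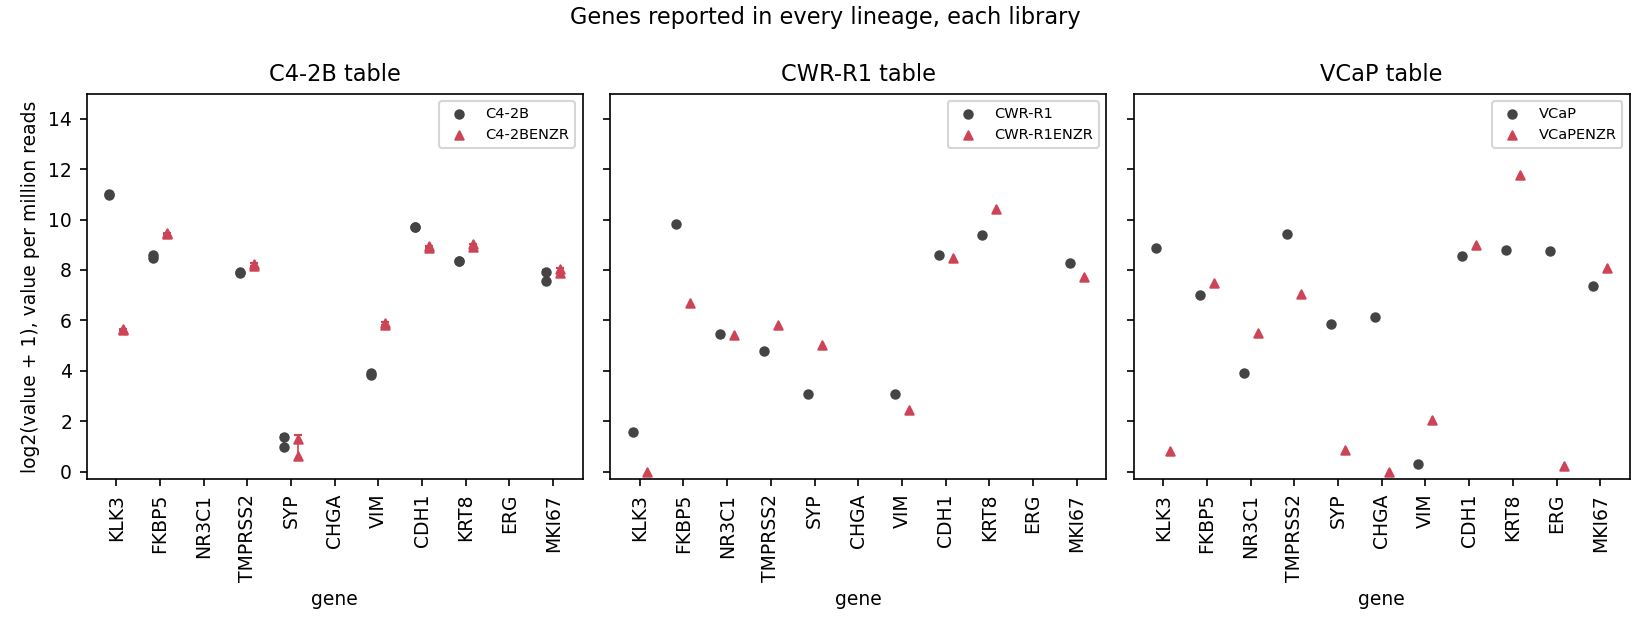
Level of 11 genes chosen before the data were examined, 1 panel per table, as log2(value + 1) per library, with sensitive and resistant libraries side by side. Each point is 1 library. KLK3 was lower in C4-2BENZR than in C4-2B, and ERG was at 428 in VCaP and at 0.179 in the library labelled VCaPENZR.

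Of 34 gene lists tested in C4-2B, 12 passed the threshold with a preset correlation between genes and 0 passed with an estimated one. The estimated version rests on 2 residual degrees of freedom, so it could hardly pass any list and cannot decide a call. Adjusted p-values with an estimated correlation are given in each case. The mesenchymal list was higher: 9 of 13 members rose and 2 fell (median 0.91, adjusted p = 0.00226, and 0.547 with an estimated correlation). FN1, which encodes fibronectin, rose from 217 ± 9.24 to 932 ± 58.9, the matrix metalloproteinase MMP14 rose 18.7-fold and the matrix protein TNC was at least 36.1-fold higher, while LOX fell 8.65-fold. In the interferon response list, 22 of 33 members rose and 2 fell (median 0.67, adjusted p = 0.000417, and 0.547 with an estimated correlation). PARP14 rose 3.90-fold to 52.1 ± 1.98 and UBE2L6 rose from 0.853 to 13.9 ± 3.02, and the antiviral tether BST2 fell 9.82-fold. This call was lost without C4-2BENZR replicate 1 (median 0.31) and without C4-2BENZR replicate 2 (0.46), but on fewer members. The low-value filter then drops rising members under 1 in C4-2B, such as UBE2L6 and IFIT2 (0.361). The lost call is therefore not a test of the replicate alone. In the WNT list, 10 of 16 members rose and 3 fell (median 0.41, adjusted p = 0.0192, and 0.547 with an estimated correlation), with the ligand WNT5A at 20.7 ± 0.645 against 1.29 ± 0.289 and the transcription factor LEF1 6.67-fold higher at 23.1 ± 4.82, and the receptor FZD8 2.69-fold lower. In the neuroendocrine list, 4 of 8 members rose and 0 fell (median 0.56, adjusted p = 0.0398, and 0.547 with an estimated correlation). ENO2, neuron-specific enolase, rose from 4.16 ± 0.245 to 32.9 ± 0.808, UCHL1 from 0.155 to 6.20 ± 0.657 and PEG10 3.18-fold. The neuroendocrine call was lost with total counts as the only scaling (camera adjusted p = 0.0669). It was also lost without C4-2BENZR replicate 1 (median 0.35), but UCHL1, under 1 in C4-2B, then missed the low-value filter.

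The list with the smallest adjusted p was that of ATF4 targets and the unfolded protein response, in which 23 of 30 members fell and 2 rose (median −0.60, adjusted p = 9.47e-09, and 0.547 with an estimated correlation). SLC7A11, the cystine transporter, fell 5.99-fold from 201 ± 6.80 to 33.5 ± 0.201, CHAC1 fell 3.74-fold, TRIB3 3.27-fold and the asparagine synthetase ASNS 2.51-fold, while SDF2L1 rose. Replication-dependent histone genes, whose symbols share near-identical copies and are uncertain one by one, fell in 13 of 14 cases (median −1.56, adjusted p = 3.24e-06, and 0.547 with an estimated correlation). HIST1H2BK went from 214 ± 2.22 to 38.1 ± 1.94 and HIST1H1C from 127 ± 5.64 to 29.3 ± 1.88. The cholesterol synthesis list was lower (18 of 24 fell, 2 rose, median −0.28, adjusted p = 0.00167, and 0.547 with an estimated correlation), with squalene synthase FDFT1 at 278 ± 10.5 against 544 ± 28.5 and the sterol carrier STARD4 7.63-fold lower. So was the NRF2 list (13 of 23 fell, 4 rose, median −0.20, adjusted p = 0.00746, and 0.689 with an estimated correlation), with NQO1, a quinone reductase, 2.53-fold lower and the malic enzyme ME1 3.01-fold lower.

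Each of the remaining calls was lost without C4-2BENZR replicate 1. That fit sets 1 library against 2, so its spread comes from C4-2B alone. A lost call does not by itself show dependence on that replicate. G2/M genes were lower (24 of 35 fell, 2 rose, median −0.23, adjusted p = 0.00138, 0.547 with an estimated correlation and 0.0650 without that library), with cyclin CCNA2 at 58.6 ± 2.62 against 102 ± 3.87 and CDK1, which rose, at 527 ± 8.17 against 423 ± 31.7. Oxidative phosphorylation genes were lower (25 of 42 fell, 8 rose, median −0.22, adjusted p = 0.00428, 0.689 with an estimated correlation and 0.0652 without that library), with SDHA, a subunit of succinate dehydrogenase, at 125 ± 5.48 against 234 ± 3.80 and CYC1 at 256 ± 20.2 against 385 ± 8.02. Ribosomal protein genes were lower (22 of 34 fell, 3 rose, median −0.18, adjusted p = 0.00226, 0.689 with an estimated correlation and 0.0727 without that library), with RPS14 at 657 ± 26.1 against 993 ± 42.5. In the lineage identity list, 6 of 8 fell and 0 rose (median −0.37, adjusted p = 0.0132, 0.547 with an estimated correlation and 0.0821 without that library), including the tumour suppressor RB1 at 43.7 ± 0.877 against 69.6 ± 4.03 and the prostate homeobox gene HOXB13 at 360 ± 9.25 against 517 ± 1.26. SLC7A11, CCNA2, STARD4, SDHA and AMACR lie in stretches of neighbouring genes that were lower as a group, and without the genes of the 10 stretches that moved most, in either direction, the medians were −0.59 for the ATF4 list, −0.23 for G2/M, −0.28 for cholesterol synthesis, −0.21 for oxidative phosphorylation and −0.42 for lineage identity.

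The other 21 tested lists did not pass besides the androgen-activated list. Their medians were 0.51 for stem and progenitor genes, 0.28 for ABC efflux transporters, 0.27 for NF-kB and inflammatory genes, 0.20 for MHC class I presentation, 0.15 for Polycomb and chromatin regulators, 0.09 for homologous recombination, 0.07 for apoptosis regulators, 0.07 for cancer-testis genes, 0.05 for p53 targets, 0.03 for G1/S genes, −0.17 for immediate early genes and −0.24 for androgen synthesis. The medians of fatty acid genes (−0.08) and glycolysis genes (−0.02) turned positive with total counts as the only scaling (0.02 and 0.09). Signs differed within a list for glucocorticoid targets (median −0.23, mean 0.14, test lower), luminal genes (−0.17, 0.02, lower), basal genes (0.25, 0.21, lower), heat shock genes (0.03, −0.01, higher), NOTCH genes (0.14, 0.03, lower), glycolysis genes (−0.02, −0.02, higher) and receptor tyrosine kinases (0.02, 0.04, lower). Fatty acid genes and receptor tyrosine kinases passed as lower when either C4-2BENZR replicate was left out, the second with medians of −0.15 and −0.30. The low-value filter then drops any member at 1 or more only in C4-2BENZR, so these results can rest on other members. With fry both passed too (0.00523 and 0.0190), and fatty acid genes also with the replicate as a block (0.0314). B2M, the light chain of MHC class I, rose 2.43-fold to 247 ± 7.87, and SGK1, a glucocorticoid target, rose 8.13-fold. Markers of fibroblasts, endothelium and blood had 2, 4 and 2 members above the low-value filter and were not tested: COL1A1 was at 50.8 ± 3.72 against 13.7 ± 1.97, VWF at 3.71 against 7.39 and HBA1 at 0.408 against 2.71.

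The test covered 13280 genes, of which 3691 rose and 3856 fell (limma, adjusted p below 0.05, groups of 2 libraries each), 56.8% of the genes tested. The libraries are repeats of a single sensitive line and a single resistant line, so the p-values cover only the spread between libraries. They do not separate resistance from other differences between these lines. The median difference between replicates was 0.10 log2, 4436 of the calls were changes under 1.5-fold, and 1318 called genes changed at least 2-fold (818 rose, 500 fell). With total counts as the only scaling the median gene was at 0.10 and the split became 4757 higher and 2923 lower. The counts of members adjusted over the list alone equalled those over all genes except for basal genes (3 against 2 higher), oxidative phosphorylation (26 against 25 lower), stem genes (7 against 6 higher) and receptor tyrosine kinases (11 against 10 higher).

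The comparison of CWR-R1ENZR with CWR-R1 rested on 1 library per group, so its values have no replicate check and no p-value, and the 95% intervals given cover counting error only. The immunophilin gene FKBP5, an androgen-activated gene, was 8.68-fold lower in CWR-R1ENZR (897 against 103; interval 8.24 to 9.16). TMPRSS2 was 2.13-fold higher (26.2 against 55.8; 1.88 to 2.41) and KRT8 2.00-fold higher at 1355, whereas CDH1 (387 and 356) and NR3C1, the glucocorticoid receptor (43.4 and 42.2), differed by less than 2-fold. KLK3 was low in both, at 1.96 (29 reads) in CWR-R1 and without a read in CWR-R1ENZR. SYP was 4.24-fold higher at 31.8, MKI67 1.47-fold lower at 209, and VIM was at 7.56 and 4.49. CHGA and ERG are not listed in this table.

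Among the genes that differed most, TGM3, a transglutaminase, was at 0.472 in CWR-R1 and 497 in CWR-R1ENZR (1053-fold, 511 to 2619), IGFBP3, which binds insulin-like growth factors, at 2.70 and 758 (281-fold, 206 to 394), and the extracellular superoxide dismutase SOD3 66.0-fold higher at 726. The keratins KRT80 and KRT19 were 434-fold and 210-fold higher, the laminin chain LAMB3 243-fold higher, SSTR5-AS1 168-fold higher (an antisense gene, uncertain because strand use in counting is not stated) and KANK4 at least 398-fold higher. PDGFRA, a growth factor receptor, was at 517 in CWR-R1 and 0.670 in CWR-R1ENZR (772-fold, 420 to 1611), and ALB, which encodes albumin, at 191 and 1 read. ASB9 and DDC were at least 281-fold and at least 237-fold lower, IQGAP2 87.8-fold, HLF 61.2-fold, NPTX2 45.1-fold and TPPP3 41.0-fold lower.

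Of 34 lists in this lineage, 16 had a median outside the central 95% of 10000 expression-matched random lists. Random lists hold unrelated genes, so a percentile takes no account of correlation between the members of a list and is not a p-value. Immediate early genes were higher (15 of 27 at least 2-fold higher, 1 lower; median 1.42, percentile 100), with the phosphatases DUSP5 and DUSP6 43.3-fold and 10.6-fold higher and CTGF 12.3-fold higher, while MYC was 2.09-fold lower. Of 26 p53 targets, 10 were at least 2-fold higher and 0 lower (median 0.77, percentile 100): GDF15, a stress cytokine, was at 24.2 and 879, CDKN1A, the cell cycle inhibitor p21, at 52.2 and 594, and PLK2 23.6-fold higher. G1/S genes were lower (0 of 32 higher, 18 lower; median −1.07, percentile 0), for example the replication helicase subunit MCM5 at 185 and 64.6 and UHRF1 at 152 and 48.1, as were G2/M genes (median −0.42, percentile 0.06), homologous recombination genes (−0.60 at percentile 0.02) and oxidative phosphorylation genes (−0.59 at percentile 0, with ATP5B at 2866 and 1203). Androgen-activated genes had a median of −0.54 (percentile 0.11), with 4 of 24 higher and 9 lower: KLK4 was 29.9-fold lower and PMEPA1 13.5-fold lower, and the efflux transporter ABCC4 was 4.80-fold higher. Stem and progenitor genes (median 1.40, percentile 100) included ALDH1A3, 61.3-fold higher, and SOX2, 6.48-fold lower, and basal genes (3 of 5 higher, 1 lower; median 2.67, percentile 100) included LAMB3 and KRT15, and LAMA3, 6.29-fold lower. MHC class I genes (0.60 at percentile 99.96; 6 of 16 higher) included HLA-B at 73.1 and 544, a symbol uncertain because its copies share reads. Luminal genes (0.48 at percentile 99.96), interferon genes (0.59 at percentile 99.91), NF-kB genes (0.97 at percentile 99.36) and histone genes (5 measured; 0.96 at percentile 97.51) were higher, and fatty acid genes (−0.49 at percentile 0.20, with SCD at 1775 and 368) and neuroendocrine genes (−0.62 at percentile 1.22) were lower. The medians of the other 18 lists lay between percentiles 5.67 (cholesterol synthesis, −0.25) and 97.05 (apoptosis regulators, 0.28). The histone list, close to the edge, lay inside the central 95% under 5 other settings with a median about as large (0.96 to 1.04). The neuroendocrine median moved inside at a level of 20 (−0.50), and the basal and NF-kB medians at a level of 1 (0.72 and 0.54).

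In all, 12462 genes reached a level of 5 in one of the CWR-R1 libraries, and 2507 of them (20.1%) differed at least 2-fold, 1220 higher and 1287 lower in CWR-R1ENZR. With total counts as the only scaling the median gene was at 0.06 and the split turned to 1387 higher and 1109 lower. At a minimum level of 20 the count was 1634.

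The third comparison set the library labelled VCaPENZR against VCaP, again with 1 library per group and no p-value. All directions below rest on the library labelled VCaPENZR, which resembled the CWR-R1 libraries (0.940 with CWR-R1ENZR) more than VCaP (0.728). ERG, the fusion partner expressed in VCaP, was at 428 in VCaP and at 0.179 (3 reads) in the library labelled VCaPENZR, 2398-fold lower (820 to 11629). KLK3 was 601-fold lower (465 against 0.774; 351 to 1129), TMPRSS2 5.28-fold lower (684 against 130) and CHGA, which encodes chromogranin A, at least 388-fold lower (69.3 against 0). FKBP5 was at 129 and 176. NR3C1 was at 14.1 and 44.4, KRT8 was 7.72-fold higher at 3444, CDH1 was at 371 and 510, MKI67 at 165 and 271, and SYP went from 57.4 to 0.834. VIM had 4 reads in VCaP and 52 in the library labelled VCaPENZR.

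The 8 highest genes were CORO1A, an actin-binding protein of leukocytes (0.285 and 756; 2657-fold), PPP1R1B (1087-fold), NES, which encodes nestin (7.29 and 2780; 381-fold), TGM3 (710-fold), TRPS1 (2 reads and 284; interval 690 to 20591), and MAGEA4, MYEOV and CCL22, which had no read in VCaP and were at least 1734-fold, 1593-fold and 1520-fold higher. The 8 lowest were KLK2, kallikrein 2 (4945 and 0.953; 5191-fold, 3196 to 9082), THBS1, thrombospondin (2608 and 0.357), ACPP, prostatic acid phosphatase (2673-fold), SPON2 (1992-fold), PMEPA1 (1554-fold), TRPM8 (614 and 3 reads), and ITM2A and NPY, which had no read in the library labelled VCaPENZR and were at least 4316-fold and 3454-fold lower.

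In the library labelled VCaPENZR, 18 of 34 lists lay outside the central 95% of random lists. These percentiles too take no account of correlation within a list. Androgen-activated genes were lower (3 of 29 higher, 18 lower, percentile 0), as were genes raised by androgen withdrawal (−2.63 at percentile 0.01), with FOLH1, prostate-specific membrane antigen, 44.2-fold lower. Lineage identity genes (−2.65 at percentile 0), neuroendocrine genes (−2.09 at percentile 0; 9 of 16 lower) and basal genes (−3.69, or −3.57 with genes without a read at their bound, percentile 0) were lower too, with CHGB at 109 and 1 read, although ENO2 was at 14.5 and 1039. All 10 cancer-testis genes measured were higher (median 6.35, or 6.12 with genes without a read at their bound, percentile 100). A gene without a read in VCaP was compared only if it reached 5 in the library labelled VCaPENZR. The direction of such a gene was therefore fixed by the filter. MAGEA3 and CTAG1B had no read in VCaP and were at least 688-fold and 912-fold higher, and the members of these families share reads. G2/M genes (24 of 35 higher, 0 lower; 1.20 at percentile 100) included NEK2, 10.1-fold higher, and immediate early genes (20 of 26 higher; 2.00 at percentile 100) included DUSP4, 31.2-fold higher, with MYC 5.55-fold lower. ATF4 targets and the unfolded protein response (17 of 30 higher, 2 lower; 1.10 at percentile 100) included the amino acid transporter SLC7A5 at 1.88 and 475. MHC class I genes (1.63 at percentile 100), glucocorticoid targets (1.93 at percentile 100), mesenchymal genes (2.37 at percentile 99.99), NOTCH genes (1.06 at percentile 99.68), glycolysis genes (0.49 at percentile 99.0) and oxidative phosphorylation genes (0.36 at percentile 98.65) were higher, and interferon genes (−0.93 at percentile 0.28), NF-kB genes (−1.28 at percentile 1.91) and ribosomal protein genes (−0.73 at percentile 1.78) were lower. These last 3 lay inside the central 95% at a level of 20 (−0.76, −0.81 and, unchanged, −0.73), and androgen synthesis genes moved outside it at a level of 1 (−1.11). The medians of the other 16 lists lay between percentiles 3.32 (histones, −1.39) and 95.24 (NRF2, 0.41). Of 12502 genes at a level of 5 in one of both libraries, 5388 (43.1%) differed at least 2-fold, 2643 higher and 2745 lower. With total counts as the only scaling the median gene of this table was at 0.10 and the split turned to 2889 higher and 2506 lower.

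The last comparison asked which genes changed in the same direction in the 3 resistant lines, with the lineage as the replicate. The VCaP member is the library labelled VCaPENZR, which resembled CWR-R1ENZR. No gene passed (limma, 0 of 12831, smallest adjusted p = 0.829), and 685 genes had an unadjusted p below 0.05, 374 higher and 311 lower. Where no gene differs, a share of 0.05 of the 12831 genes would fall below it. The 685 genes therefore do not by themselves show shared changes. Since BAMBI, named below with large ratios in all 3 lineages, did not pass, 0 calls do not show that shared changes were absent. edgeR called 0 and DESeq2 198. DESeq2 called 10 of the 12 genes named next, all but SLC6A10P and PRUNE2. The genes with the largest shared differences are given as log2 ratios in C4-2B, CWR-R1 and VCaP. BAMBI, a decoy receptor for TGF-beta and BMP signals, was at 2.81, 3.70 and 3.05. The potassium channel subunit KCNG1 was at 2.48, 3.32 and 4.39. The GATA-type repressor TRPS1 was at 3.75 and 2.05, with a level of 0.114 (2 reads) in VCaP and 284 in the library labelled VCaPENZR. WBP5 was at 1.88, 2.60 and 4.74, and the retinoic acid hydroxylase CYP26B1 at 1.82, 2.29 and 2.03. The pseudogene SLC6A10P, uncertain because it shares reads with its parent gene, was at 2.31, 2.08 and 6.50. DDC was at −2.71, −5.60 and −6.66, the leukocyte actin-bundling gene LCP1 at −2.20, −4.48 and −8.56, PTGFR at −4.78, −2.08 and −3.83, NAV3 at −2.44, −2.27 and −3.53, PRUNE2 at −2.15, −3.23 and −6.91 and the sialyltransferase ST6GALNAC1 at −2.04, −2.01 and −4.39. Without C4-2B, which leaves the lineages whose resistant libraries resembled each other, SOD3 alone passed (log2 ratio 6.47, limma adjusted p = 0.0132). It was named after its value was seen.

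Of 34 lists, 7 passed across the lineages with a preset correlation and 0 with an estimated one (adjusted p = 0.937, and 0.999 for G1/S). The estimated version again rests on 2 residual degrees of freedom, too few to decide. With the direction of C4-2B, CWR-R1 or VCaP turned, 11, 9 and 6 lists passed with the preset correlation. The 7 calls therefore do not by themselves show a direction shared by the lineages. MHC class I genes were higher (median 1.26, adjusted p = 0.00300), as were p53 targets (0.54, adjusted p = 0.0152), immediate early genes (0.85, adjusted p = 0.000541) and cancer-testis genes (2.07, or 1.99 with genes without a read at their bound, adjusted p = 0.000541). Ribosomal protein genes (−0.37, adjusted p = 4.95e-05), cholesterol synthesis genes (−0.26, adjusted p = 0.0402) and G1/S genes (−0.24, adjusted p = 0.0296) were lower. By lineage, in the order above, the MHC class I medians were 0.28, 0.55 and 1.63, those of immediate early genes −0.11, 1.23 and 1.60, and those of cholesterol synthesis genes −0.28, −0.25 and −0.27. G1/S genes were at 0.03, −1.07 and 0.24, so their median was lower in CWR-R1 alone. Cancer-testis genes were at 0.07, 0.04 and 6.10, p53 targets at 0.05, 0.77 and 0.21, and ribosomal protein genes at −0.18, −0.21 and −0.73. Camera as run here did not match lists on expression. Among expression-matched random lists, ribosomal protein genes lay at percentile 46.8 in CWR-R1 and 1.78 in VCaP. Cholesterol synthesis genes lay at percentiles 5.67 and 22.6, and C4-2B had no such comparison. An effect of expression level on the ribosomal and cholesterol calls is therefore not excluded. Without CWR-R1 the calls for MHC class I (adjusted p = 0.0777), cholesterol synthesis (0.257), p53 targets (0.519), cancer-testis genes (0.0658) and G1/S genes (0.511, median 0.18) were lost, without C4-2B that for cholesterol synthesis (0.255), and without VCaP that for cancer-testis genes (0.307, median −0.01). Androgen-activated genes did not pass (median −0.50, adjusted p = 0.0765) and had medians of 0.22, −0.76 and −1.27. They passed without C4-2B (median −0.99, adjusted p = 0.00935) and with total counts as the only scaling (−0.40, adjusted p = 0.0407). The lineages left without C4-2B are those whose resistant libraries resembled each other.

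By size alone, 40 genes were at least 2-fold higher in all 3 resistant lines and 38 at least 2-fold lower, of 10655 genes compared. Independent lists of these sizes would share 5.53 and 4.03. With total counts as the only scaling the counts were 52 higher and 31 lower, against 8.65 and 2.49. The 40 and 38 genes include SGK1, NES, SMAD3 and the aryl hydrocarbon receptor target CYP1A1 among the higher genes, and DDC, MET, the malic enzyme ME1 and the laminin chain LAMA3 among the lower ones. These 8 were picked after their values were seen. Without VCaP, 101 genes were higher in both resistant lines and 70 lower, against 31.5 and 25.7 for independent lists. Opposite directions were in excess too in the pairs with C4-2B, over the 10655 genes: 111 genes against 53.7 with CWR-R1, where 94 were higher in both (28.9 for independent lists) and 62 lower (23.5), and 193 against 125 with VCaP, where 150 were higher in both (78.2) and 95 lower (49.4). Part of the overlap with C4-2B was therefore not particular to a shared direction. CWR-R1 and VCaP had 294 opposite against 296, with 276 higher in both against 145 and 292 lower against 149. The library labelled VCaPENZR correlated at 0.940 with CWR-R1ENZR, so their agreement is not that of independent lineages. Independent lists are then too low a reference for this pair, and for the 40 and 38 genes. Over all genes the log2 ratios of C4-2B correlated at 0.0887 with those of CWR-R1 and at 0.0381 with those of VCaP, and those of CWR-R1 and VCaP at 0.195, across genes that are not independent replicates.

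**Figure D3:**
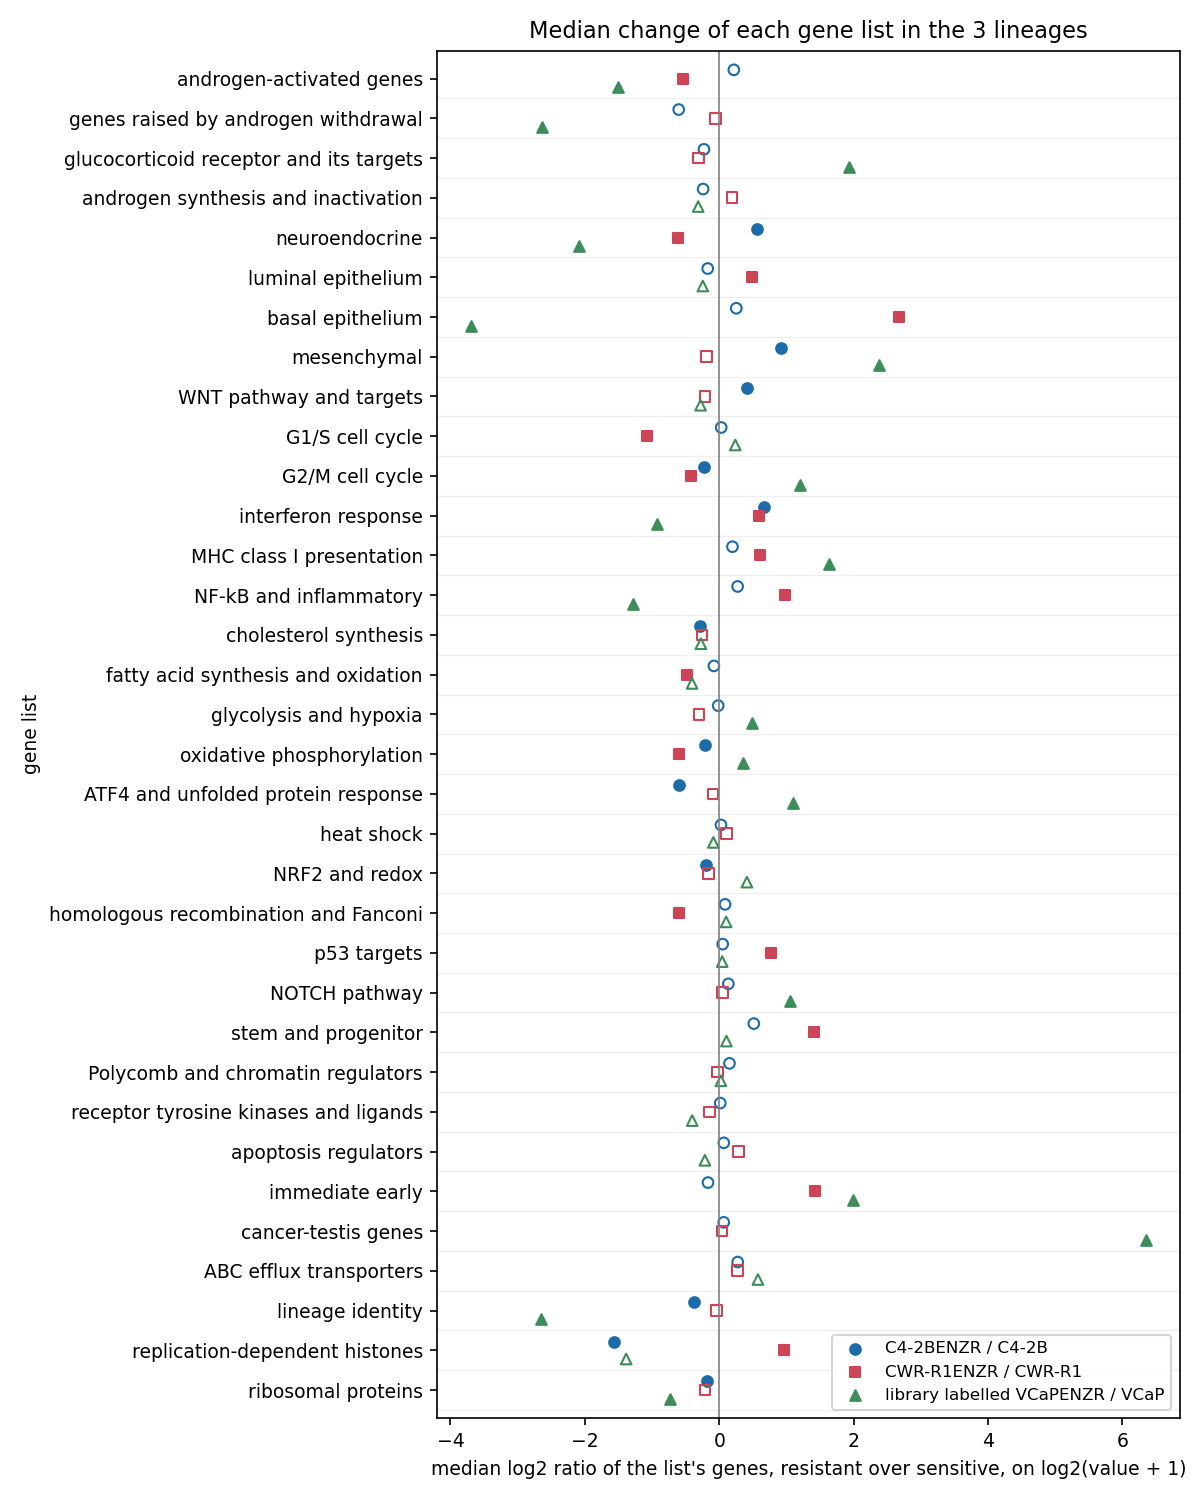
Median log2 ratio, resistant over sensitive, of each gene list in the C4-2B (circles), CWR-R1 (squares) and VCaP (triangles, library labelled VCaPENZR) tables, which were normalized separately. Filled symbols passed the camera threshold (C4-2B) or lay outside the central 95% of random lists (the other two). Cancer-testis genes reach 6.35 in VCaP, and histone genes are at −1.56 in C4-2B.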

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

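In this part the tests of the identity of the library labelled VCaPENZR and of the cell cycle behind the histone genes were chosen only after the results were seen, except the test of a response shared with CWR-R1; the tests of carry-over and of the histone region were written before their results.

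The library labelled VCaPENZR resembled the CWR-R1 libraries more than VCaP. Of 127 genes at 10 or more in both CWR-R1 libraries and under 1 in VCaP, 92.9% reached 5 in the library labelled VCaPENZR, against 20.2% of the 129 corresponding genes in C4-2BENZR, and of 38 genes at 10 or more in VCaP and under 2 in both CWR-R1 libraries, it kept a median of 1.42% of the VCaP level, against 81.8% kept by 18 such genes of C4-2B in C4-2BENZR. The second value argues against VCaP cells mixed with CWR-R1 cells (the bound of 2 replaced a bound of 1 that left no gene), and an exchange of the 2 ENZR labels is argued against by CWR-R1ENZR, whose correlation with CWR-R1 exceeded that with VCaP by 0.142. A response to enzalutamide shared by both lines, the biological explanation, is argued against by 7119 genes unchanged between CWR-R1 and CWR-R1ENZR, over which the library correlated at 0.958 with CWR-R1 and at 0.801 with VCaP, a difference of 0.157. RNA of cells of the CWR-R1 lineage under a VCaPENZR label is a candidate explanation that these values allow; whether it arose in culture, at labelling or from another line of similar origin stays open.

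Histone transcripts were lower in C4-2BENZR, with a median of −1.56 over 14 listed genes and 25 of 26 genes with a HIST symbol falling. Fewer cells in S phase is argued against as the whole cause by the G1/S genes (9 of 32 rose, 7 fell, median 0.03). Their lower quartile was −0.11 and their lowest member, MCM3, was at −0.47. G2/M genes were lower (24 of 35 fell, 2 rose, median −0.23), so a smaller part of it in the pattern is not excluded. Fewer copies of the region that holds most histone genes is argued against by the 15 other genes inside it, with a median of 0.19 (3 fell, 6 rose), and by the 9 HIST genes elsewhere, with a median of −1.68. Less carry-over of RNA without a poly(A) tail cannot be told apart from a change in the histone transcripts, because only 4 such RNAs were measured (median −0.14; RN7SL1 and RN7SL2 fell, RN7SK and SNORD17 did not differ). Carry-over, or a larger share of polyadenylated histone transcripts in C4-2B, may account for the pattern and stays open.

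Of 57 named genes, 17 moved in opposite directions in different lineages, as did 8 lists. Most of the 57 were picked for the largest changes in a lineage, and 43.1% of the genes compared in VCaP differed at least 2-fold. No reference count was made, so 17 of 57 does not show an unusual share. A gene counted if it differed at least 2-fold in both lineages (in C4-2B with an adjusted p below 0.05 and groups that do not overlap), a list if it passed in both. The differences between lineages were not tested, and most rest on the library labelled VCaPENZR; values are log2 ratios, resistant over sensitive.

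SYT4 was at 5.92 in C4-2B, −3.76 in CWR-R1 and −6.20 in VCaP. BEX1 was at 5.07 in C4-2B and 2.61 in CWR-R1 but −4.87 in VCaP. KCNJ3 was at 6.24 in C4-2B and −4.82 in VCaP. TENM2 was at 5.24 in C4-2B and −4.01 in CWR-R1. IGFBP3 was at 2.43 in C4-2B, 7.68 in CWR-R1 and −3.55 in VCaP. THBS1 was at 1.44 in C4-2B, −1.33 in CWR-R1 and −10.91 in VCaP. ALB was at 1.24 in C4-2B, −7.49 in CWR-R1 and −5.51 in VCaP. Among androgen-activated genes, KLK2 was at 1.01 in C4-2B and −11.31 in VCaP, and TMPRSS2 at 1.06 in CWR-R1 and −2.39 in VCaP. PCDH7 was at −5.83 in C4-2B and 4.02 in VCaP, and PCDH20 at −4.54 and 3.53. TFPI was at −4.19 in C4-2B and 3.42 in VCaP, and TM4SF1 at −4.30 in C4-2B and 3.64 in CWR-R1. HLF was at −5.29 in CWR-R1 and 2.47 in VCaP, TPPP3 at −5.04 and 3.07, SSTR5-AS1 at 6.53 and −1.72, and SYP at 1.95 and −4.99.

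Neuroendocrine genes had medians of 0.56 in C4-2B, −0.62 in CWR-R1 and −2.09 in VCaP. Interferon genes were at 0.67 in C4-2B, 0.59 in CWR-R1 and −0.93 in VCaP, G2/M genes at −0.23, −0.42 and 1.20, and oxidative phosphorylation genes at −0.22, −0.59 and 0.36. ATF4 targets and the unfolded protein response were at −0.60 in C4-2B and 1.10 in VCaP, and histone genes at −1.56 in C4-2B and 0.96 in CWR-R1. Basal genes were at 2.67 in CWR-R1 and −3.69 in VCaP, and NF-kB genes at 0.97 and −1.28. Of these CWR-R1 medians, those of basal and NF-kB genes moved inside the central 95% of random lists at a level of 1 (0.72 and 0.54), the neuroendocrine one at a level of 20 (−0.50) and the histone one, about as large at 0.96 to 1.04, lay inside under 5 settings, and in VCaP those of interferon and NF-kB genes did at a level of 20 (−0.76 and −0.81). In C4-2B every one of these calls was lost with an estimated correlation, which could hardly pass any list. The neuroendocrine, interferon, G2/M and oxidative phosphorylation calls were lost without C4-2BENZR replicate 1, and the interferon call without C4-2BENZR replicate 2. Members under 1 in C4-2B, such as UCHL1 and UBE2L6, then missed the low-value filter, so the neuroendocrine and interferon lists had fewer members. The neuroendocrine call was also lost with total counts as the only scaling (camera adjusted p = 0.0669). Each median above is over the members measured in that lineage, which differ between lineages. Over the members tested in all 3 tables, basal genes were at 2.67 in CWR-R1 and 0.57 in VCaP, no longer in opposite directions. Neuroendocrine genes were then at 0.23 in C4-2B, −0.22 in CWR-R1 and −0.52 in VCaP. NF-kB genes were at 0.72 in CWR-R1 and −1.03 in VCaP, and the other lists also kept opposite directions.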

How the results depend on the processing

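Counts of called genes in C4-2B lay between 5921 and 8318 under all alternatives except a 2-fold minimum (1318), with leave-outs giving 5962 to 6804. Of the named C4-2B genes, 3042 comparisons with an alternative kept direction and side and 72 lost the call; the cause was not tested. The 12 lists passed in C4-2B became 0 with an estimated correlation, which rests on 2 residual degrees of freedom and could hardly pass any list. With fry they became 23, but fry asks whether members change, not whether they change more than other genes. With fry glucocorticoid targets turned from lower to higher by the test (median −0.23, adjusted p = 0.0374). In CWR-R1 the count fell to 1634 at a level of 20, where fewer genes were compared, and receptor tyrosine kinases turned to 0.47 at a level of 1; in VCaP they turned to 0.90 at a level of 20, each time over other members. Across lineages 198 genes passed with DESeq2 and 0 to 1 with a lineage left out; the cause was not tested. The 7 lists became 0 with an estimated correlation and 4 to 12 with a lineage left out; G1/S ranged from −0.49 to 0.18 and turned without CWR-R1, and G2/M from −0.33 to 0.55 and turned without VCaP. Overlap counts were 254 at 1.5-fold, 9 at 4-fold and 171 without VCaP. In CWR-R1 985 gene values and 226 list medians kept their place, 25 and 8 moved and 1 list turned; in VCaP 1193 and 231 kept it, 26 and 4 moved and 1 list turned. All 51 moved gene values were those with total counts only. The prior count of 2, the overlap without VCaP, single C4-2B replicates for the lists across lineages, and edgeR with its own scaling (with or without a replicate block) or on summed reads were chosen after seeing the data; the other edgeR fits were planned. The planned limma alternative across lineages is the fit reported. Depth limits genes near the floor of 3 reads.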

Other observations

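In this part the tests of chance order and of copy number and the splits of the samples were chosen only after the results were seen; the test of GC content and length was written before its result.

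Some genes of C4-2BENZR that stand in lists without a call, picked after their values were seen, changed in both directions (SD, n = 2 libraries per group; limma). The growth factor IGF1 fell 7.88-fold, from 104 ± 4.14 to 13.2 ± 0.427, its receptor IGF1R fell 6.08-fold, from 198 ± 3.67 to 32.5 ± 4.95, EGF fell 9.46-fold, and the binding protein IGFBP3 rose 6.76-fold. SLC16A3, a lactate exporter, fell 12.8-fold from 358 ± 0.207, lipoprotein lipase LPL fell 16.1-fold, the fatty acid elongase ELOVL7 fell 8.48-fold from 638 ± 48.4 and ACSL1, an acyl-CoA synthetase, fell 3.43-fold. In the same lists ELOVL2 rose 3.31-fold, ACSL3 1.92-fold, CA12 2.66-fold, ALDOC 2.06-fold and SLC2A3 2.96-fold. The stress cytokine GDF15 fell 5.30-fold, PHLDA1 fell 7.34-fold, and the cancer-testis gene CTAG2, whose reads may be shared with related copies, rose 15.6-fold to 87.3 ± 6.80. NOTCH3 rose 2.24-fold and NOTCH1 fell 1.99-fold.

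Genes that neighbour each other moved together in C4-2BENZR: in the gene order of GRCh38.p14 (93.0% of 11048 genes placed), log2 changes of genes 50 places apart correlated at 0.0811, against at most 0.0223 in 100 shuffled orders, which argues against chance order. After a fit on GC content and transcript length (99.5% of placed genes) the correlation was 0.0769, from 0.0817 before it, which argues against these as the whole cause. Copy number differing between the lines over long stretches is a candidate explanation that stays open: in the 10 stretches picked on every other gene, 82.8% of 290 left-out genes lay on the stretch's side, and 63.1% over all 157 stretches. The left-out genes had medians of −0.55 from WASH5P to SGTA, −0.49 from CAMK2D to ARFIP1, −0.46 from PSPC1 to KBTBD6, −0.36 from ERAP1 to SLC22A5 and −0.31 from SDHA to PRKAA1, and of 0.53 from BZW2 to POLR2J4, 0.43 from PRKAR1B to DGKB, 0.24 from CAMTA2 to PER1, 0.23 from RIMKLB to ALG10 and 0.11 from KRT10 to FAM171A2. The corresponding correlations were 0.0711 in CWR-R1 (shuffled at most 0.0226) and 0.0372 in VCaP (0.0353), and no DNA measurement was used here.

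The 3 lineages allow 4 ways to turn the direction of single lineages, too few for a share under 0.05. For genes, the real assignment gave 0 calls and the highest other gave 0, so 4 of 4 gave as many. For lists, the real assignment gave 7 and the highest other 11, and 3 of 4 gave as many.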
